A study of Drosophila melanogaster with 3 samples.

How the data were processed

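CG2199-bound DNA was measured by ChIP-seq with an anti-GFP antibody in 3 biological replicates of whole embryos aged 8 to 24 hours that express CG2199 fused to GFP. The age follows the source name in the labels, because their age field holds a different number that is no plausible age in hours. Chromatin was sonicated, and the labels give a size range of 200 to 800. The replicates form 1 group, taken from the labels. A control experiment named in the labels was not analysed here. The 14 peak lists used comprise a ranked and a thresholded list for each replicate (6 lists) and 8 lists of the whole series.

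Per the file descriptions, the authors derived peak lists by irreproducible discovery rate (IDR) from alignments to dm6. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists hold a scaled IDR score of at most 1000 for each peak, and the thresholded lists hold scores of 830 or more. The deposited ranked lists also hold the -log10 of the global IDR for each peak, and a score of 830 corresponds to an IDR of 0.01. The deposited signal value is another measure of enrichment made by the authors, whose unit and scaling are not stated, so signals were compared only within a list, and replicate means are means of such values. The series-level list that the authors named conservative served as the main list. Its 2 peaks off the chromosome arms were left out. Each thresholded list also leaves out some peaks of its ranked list that reach the score: 195 for the conservative list and 126, 116 and 130 for replicates 1, 2 and 3. The read depth is unknown, so no floor or interval for reads can be given. Intervals of shares are Wilson 95% intervals over peaks or genes. The interval of the odds ratio of promoter peaks and that of the ratio of shares use a normal approximation on the log scale. That of the ratio of densities uses a normal approximation of the count. Odds ratios of gene lists have conditional exact intervals, and the lower limit for strong peaks is exact. All intervals cover counting error only.

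Genes and start sites came from Ensembl release 115 (BDGP6.54), and sequence from the RefSeq assembly release 6. The 13968 protein-coding genes on 2L, 2R, 3L, 3R, 4, X and Y were used. A gene counted as bound if a summit lay within 500 bp of any of its TSSs, and a peak beyond 2000 bp of any TSS counted as distal. A summit within 100 bp of another list's summit counted as shared. Sharing was tested against 1000 placements of summits at random positions of the same chromosome, and promoter shares against 1000 random sets, both one-sided. Genomic categories used 200 random sets. Weak peaks were pooled ranked peaks of below-median signal over 1000 bp from conservative peaks. Motifs and 6-mers were counted in 50 bp either side of summits, against weak peaks matched on promoter class and on GC content in bins of 5%. The 6-mers were found on 2L, 3L and X and tested again on 2R, 3R and 4. Shares were compared by two-sided Fisher's exact tests, and medians of signal by permutation with 100000 resamples. The p-values were adjusted by Benjamini-Hochberg over 7 arms, 19 motifs, 2080 6-mers or 21 gene lists, with a threshold of 0.05. Gene lists, motifs and tests were chosen before the data were examined, except those named in the texts as chosen later. Named genes followed a rule of the same date. They are CG2199, the protein-coding genes nearest to the 25 strongest conservative peaks found in all 3 replicates, up to 4 strongest bound members of each list, and the genes nearest to the 5 strongest distal peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

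The procedures were tested on simulated data. Planted sharing of 40% was measured as 40.3%, and a planted promoter share of 39.7% as 39.6%. A planted 6-mer was recovered in both sets of arms, and 0 of the 2080 6-mers passed with nothing planted. The list of 91 cytoplasmic ribosomal protein genes, with a further 25% of its members bound, was called in 100% of 100 simulations. No other list was raised in this way, so the chance of calling a smaller list is unknown. With nothing planted, any list was called in 3% of 400 simulations when genes were bound independently and in 9% when neighbours shared summits.

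The alternatives were summit distances of 50 and 250 bp, an overlap of 1 bp and a reciprocal overlap of 50%. Promoter windows of 250 and 1000 bp and the TSSs of protein-coding genes were also used. So were the 50% of the conservative list with the larger signal and the largest thresholded list. Motif windows of 100 and 25 bp either side of summits and flanking windows at 500 bp were further alternatives. Random ranked peaks were a background for sharing, and genes with a ranked summit a background for lists. Each replicate was also left out in turn, keeping conservative peaks found in both others. Alternatives added after the data were seen left out summits in coding exons for motifs and 6-mers, gave the signal agreement of each pair, searched the CG2199 locus in the largest and the pooled ranked list, counted each summit only for its nearest TSS in the test of divergent promoters, and took weak peaks at any distance over 100 bp from conservative peaks. Other kinds of gene were compared with protein-coding genes matched on TSS number. Peaks on the ribosomal DNA scaffold and other scaffolds were left out of all comparisons.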

Results

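DNA bound by CG2199 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 8 to 24 hours. The embryos carried a transgene for CG2199 fused to the green fluorescent protein GFP, and an anti-GFP antibody was used. CG2199, also named indra, encodes a zinc-finger protein known to bind ribosomal DNA. There was 1 group with 3 biological replicates. No control library was among the samples. The labels name a control experiment, which was not analysed here, so no comparison between groups was possible. All values derive from the authors' peak lists on the dm6 assembly. The read depth of the libraries is unknown, so intervals given below cover only the counting of peaks or genes. The thresholded lists held 2813, 2601 and 3020 peaks in replicates 1, 2 and 3, a mean of 2811 ± 210 (SD, n = 3). The authors' list called conservative held 5640 peaks, of which 5638 lay on chromosome arms 2L, 2R, 3L, 3R, 4 and X. Its signal value is the authors' enrichment measure, and its unit is not given in the sources used here.

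The first comparison asked whether the replicates found the same sites. Of the peaks of a replicate, 48.5% to 56.3% had a summit of another replicate within 100 bp, over the 6 ordered pairs. Randomly placed summits gave 0.443% to 0.522%, and random peaks drawn from the unthresholded ranked lists gave 2.30% to 2.83%. In each ordered pair the one-sided permutation p was 0.001, the smallest that 1000 placements can give. Across the shared peaks of a pair, the signals of both replicates had a Spearman rho of 0.60 for replicates 1 and 2. The rho was 0.637 for replicates 1 and 3 and 0.671 for replicates 2 and 3. These are correlations across 1381, 1474 and 1464 peaks, which are not independent replicates. Of the 5638 conservative peaks, 1072 (19%, Wilson 95% interval 18% to 20.1%) were found in the thresholded lists of all 3 replicates, and 2214 (39.3%) in none. The share found in all 3 was 75% in the fifth of peaks with the largest signal and 0% of 1128 in the fifth with the smallest. A count of 0 is no evidence of absence here, because thresholded lists are limited by the reproducibility score. The ranked list behind the conservative one, of 113766 peaks, holds signal values of the inputs compared. These matched values of replicate 1 in 84.5% and of replicate 3 in 85.7% of its peaks, which points to these 2 as inputs of the conservative list.

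The strongest site found in every replicate lay between genes on 2L. Its peak spanned 7628583 to 7628933 and its summit lay 20377 bp downstream of the nearest protein-coding start site, that of CG6739 (FBgn0031926). It had a signal of 1929.9 in the conservative list and 633 ± 83.5 (SD, n = 3) in the replicates, where it ranked 1 in each. The second strongest had a signal of 1153, so the first was 1.67 times higher. That second site had its summit on X at 2703898, at -46 bp from the start of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. Its signal was 385 ± 79.9 in the replicates. Next came an intron of Samuel (FBgn0032330) on 2L at 11066462, with 1148, and a site on 3L at 19590610, at -86 bp from CG14100 (FBgn0036889), with 1065. Of the 25 strongest peaks found in every replicate, 16 had a summit within 500 bp of a transcription start site (TSS), and 15 of those lay upstream of it. A further 4 lay between 500 and 2000 bp from a TSS and 5 lay beyond 2000 bp. The signals of the 25 ranged from 667 to 1929.9, and 23 different genes were nearest to them. HmgZ (FBgn0010228), which encodes an HMG-box protein, was nearest to 2 peaks on 2R, with 906 and 667. The Polycomb group gene ph-p (FBgn0004861) had a peak on X at 2137347 with 826, and Chro (FBgn0044324), which encodes the chromodomain protein Chromator, had a peak on 3L at 22878870 with 690. The other genes nearest to the 25 were toc, with 2 peaks, CG7601, CG11050, Kank, px, CG6280, CenG1A, Tcs5, Art3, CG1888, PNPase, l(1)G0196, CG13323, Act79B, mRpL41 and CG18549. The 5 strongest peaks beyond 2 kb from a TSS were those nearest to CG6739, CG6280, l(1)G0196, CG13323 and Act79B, with signals from 683 to 1929.9. The peak in l(1)G0196 (FBgn0027279) lay in a coding exon, on X at 22502425, and the other 4 were intergenic.

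CG2199 peaks lay at promoters more often than random positions and weak peaks. Of the 5638 conservative summits, 39.3% (Wilson 95% interval 38.0% to 40.6%) were within 500 bp of an annotated TSS, against 13.5% ± 0.439 (SD over 1000 random sets). The share was 41.9% ± 0.762 (SD, n = 3) in the replicates. Introns held 37.6% of the conservative summits and intergenic sequence 17.0%. Coding exons held 2.00%, against 14% of random positions and 24.6% of weak peaks. The one-sided permutation p against random positions was 0.001, the smallest that 1000 sets can give. Weak peaks, meaning ranked peaks of below-median signal over 1 kb from any conservative peak, were at promoters in 15.1% of 53497 cases. The odds ratio against them was 3.63 (95% interval 3.43 to 3.85 by a normal approximation). The p of a two-sided Fisher's exact test was under the smallest floating-point number. Leaving out the 1 kb around conservative peaks also leaves out some promoters, so the weak peaks were counted again over 100 bp from conservative peaks, a choice made after the data were seen. They were then at promoters in 15.7% of 57337 cases (odds ratio 3.48).

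**Figure D1:**
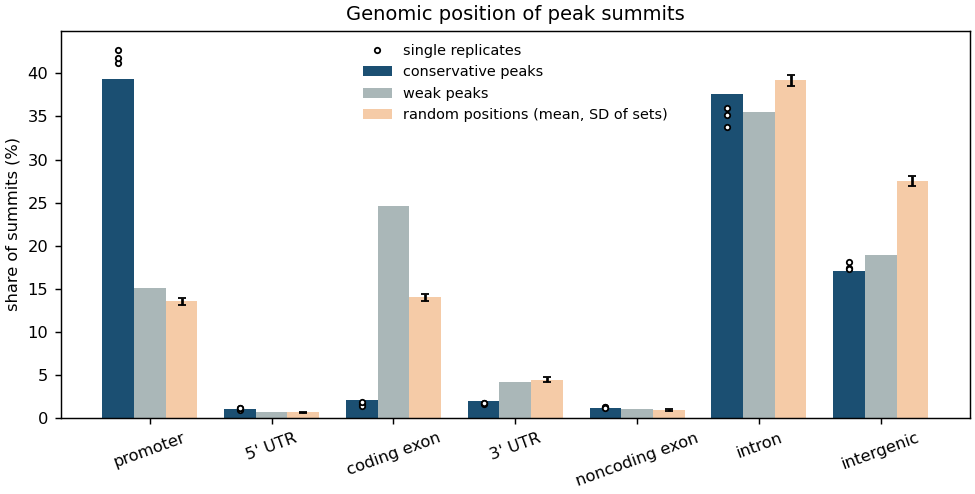
Share of summits in percent (y axis) in each genomic category (x axis) for the conservative list, weak peaks and random positions, with the mean and SD of 200 random sets and open circles for the 3 replicates. Promoters hold 39.3% of conservative summits against 15.1% of weak and 13.5% of random ones, and coding exons hold 2.00%, 24.6% and 14%.

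At promoters, CG2199 summits lay more often upstream of the start site than downstream. Of the 2216 summits within 500 bp of a TSS, the median position was -29 bp. Of the 2209 that did not lie exactly on the nearest TSS, 57.8% lay upstream of it. In the replicates 62.3% ± 3.60 (SD, n = 3) lay upstream. A two-sided test against 100000 resamples with an even chance of either side gave a resampling p of 1e-05, the smallest it can give. The test takes summits as independent, and the upstream share of random positions or weak peaks was not measured. Between start sites that point away from each other a summit is upstream of both, so an even chance need not hold without a preference. Promoters that start genes in both directions were compared with others. Of the 1907 protein-coding genes with a conservative summit within 500 bp of a TSS, called bound here, 38.1% had a start site on the other strand within 500 bp upstream. Among the 12061 other protein-coding genes this share was 28.3% (odds ratio 1.56, two-sided Fisher's exact p = 1.49e-17). It was 38.8% ± 2.19 (SD, n = 3) among bound genes of the replicates. Both genes of such a pair can be counted through 1 summit, which raises their share by construction. With each summit counted only for its nearest TSS, a choice made after the data were seen, the share was 28.2% of 1604 bound genes and 29.8% of 12364 others (odds ratio 0.925, two-sided Fisher's exact p = 0.191). This second count lowers the share by construction, since the other gene of a pair then counts as unbound. The 2 counts are biased in opposite directions, so they do not decide whether such promoters differ.

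**Figure D2:**
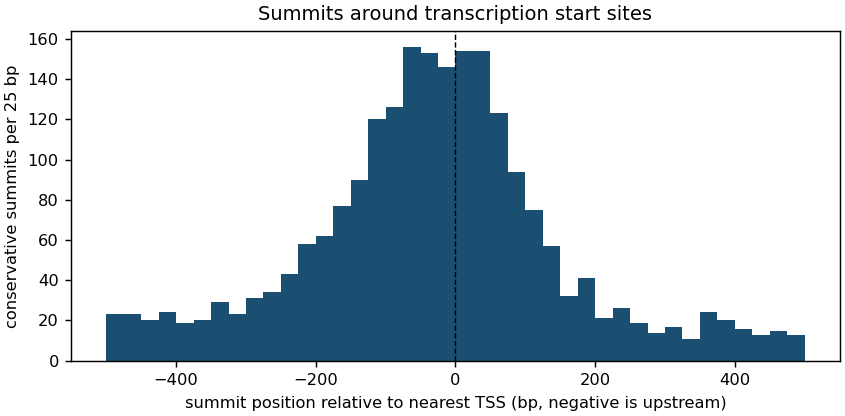
Number of conservative summits per 25 bp (y axis) by position relative to the nearest TSS in bp (x axis, negative is upstream), for summits within 500 bp. The dashed line is the TSS, and 57.8% of the 2209 summits not exactly on it lie to its left.

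The signal of promoter peaks was compared with that of distal peaks. Of the conservative peaks, 36.2% (2042) were over 2 kb from any TSS. The median signal was 123 at the 2216 promoter peaks and 116 at the distal ones, a difference of 7.01. The two-sided permutation p was 1e-05, the smallest that 100000 resamples can give. It was 7.42 in the largest list and 12.3 in the stronger 50% of the conservative list (permutation p = 1e-05 in each). With only the peaks found in both remaining replicates it was -0.363 without replicate 1 (permutation p = 0.924), 4.03 without replicate 2 (p = 0.30) and 4.24 without replicate 3 (p = 0.457). The sets without a replicate and the stronger 50% are selected by signal, so they do not test this difference.

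Chromosome 4, a short chromosome rich in heterochromatin, had the largest share of bound genes. Of its 80 protein-coding genes, 42 were bound (52.5%, Wilson 95% interval 41.7% to 63.1%), against 13.4% on the other arms (odds ratio 7.13, adjusted exact p = 1.07e-15). In the replicates the share was 40.8% ± 3.15 (SD, n = 3). Chromosome 4 also had 162 conservative peaks per Mb, against 26.7 on X and 39.2 to 48.5 on the arms of chromosomes 2 and 3. Of its 219 conservative peaks 27.9% lay at promoters, a smaller share than the 35.8% to 44.3% on the other arms with peaks. On X, 10.3% of 2196 genes were bound against 14.3% elsewhere (odds ratio 0.689, adjusted exact p = 1.07e-06), and 6.07% ± 0.467 (SD, n = 3) in the replicates. On 3L the share was 15.4% of 2739 genes against 13.2% elsewhere (adjusted exact p = 0.00744). The arms 2L (14.6%), 2R (13.5%) and 3R (13%) did not pass the threshold. On Y 0 of 23 genes were bound, which allows a share of up to 13%, and the test did not pass (adjusted exact p = 0.111). Each arm was compared with all others by a two-sided Fisher's exact test, adjusted over 7 arms. Peaks that reach the score but were left out of the thresholded lists were uneven over arms. For the pooled ranked list 129 lay on 3R, 61 on 2L, 18 on 3L, 10 on 2R and 1 on X. Whether this changed the shares of bound genes was not tested. With only the peaks found in both remaining replicates, the chromosome 4 difference stayed past the threshold at 20.3 to 24.1 percentage points, against 39.1 in the full list. The X difference of -3.99 points became -1.28, -1.26 and -1.09 without replicates 1, 2 and 3 (adjusted exact p = 0.0330, 0.0368 and 0.0849). The 3L difference of 2.18 points became 0.629, 0.936 and 0.483 (adjusted exact p = 0.253, 0.0956 and 0.390). Fewer genes were bound in these sets. The Y difference, with 0 genes bound, was -13.7 points in the full list and -4.87 to -4.47 in them. Points in these sets therefore do not compare with points in the full list. The 3L call was also lost with a promoter window of 250 bp (1.37 points, adjusted exact p = 0.0794).

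**Figure D3:**
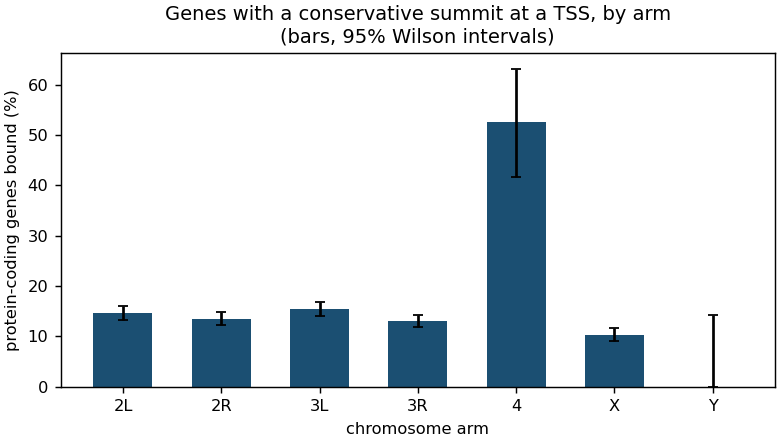
Share of protein-coding genes in percent (y axis) with a conservative summit within 500 bp of a TSS, for each chromosome arm (x axis), with Wilson 95% intervals. Chromosome 4 stands at 52.5% and the arms 2L, 2R, 3L, 3R and X between 10.3% and 15.4%.

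Sequences known from other DNA-binding proteins were counted in the 101 bp around each summit. The GAGA repeat, bound by GAGA factor, was in 3.85% of 5638 peaks and 1.21% of as many matched weak peaks (odds ratio 3.28, adjusted exact p = 1.82e-18). The core motif of the insulator protein CTCF was in 6.53% against 3.67% (odds ratio 1.83, adjusted exact p = 5.24e-11). The motif of su(Hw), also an insulator protein, was in 1.12% against 0.514% (adjusted exact p = 0.00229), and that of BEAF-32 in 15% against 12.7% (adjusted exact p = 0.00229). The GATA motif was in 17.7% against 15.3% (adjusted exact p = 0.00280), and the shared motif of Exd and Hox proteins was lower, with 1.40% against 2.15% (adjusted exact p = 0.0106). The DRE, a promoter element, was in 0.656% of both sets, but it was more frequent at peaks of the largest list (0.554 points, adjusted exact p = 9.76e-05). The 6 motifs named first were the ones that passed out of 19 tested by two-sided Fisher's exact tests, matched on promoter class and GC content. The GAGA and CTCF calls held in the sets without replicates 1, 2 or 3 and in the stronger 50% of the list. They also held in a window of 25 bp either side of the summit. That window ended the calls of BEAF-32, su(Hw), Exd/Hox and GATA (0.887 percentage points for GATA, adjusted exact p = 0.217). A set without replicate 1 ended that of su(Hw) (0.647 points, adjusted exact p = 0.25). Sets without replicate 1 or 3 ended that of Exd/Hox (-1.36 and -1.21 points, adjusted exact p = 0.0642 and 0.0818). Sets without replicates 1, 2 and 3 moved the CTCF difference from 2.86 points to 6.11, 5.48 and 5.65, that of BEAF-32 from 2.32 to 4.45, 3.84 and 3.92, and that of GAGA from 2.64 to 2.30, 1.85 and 1.58. The su(Hw) difference of 0.603 became 1.03 without replicate 2 and 1.28 without replicate 3, and that of Exd/Hox went from -0.745 to -1.51 without replicate 2. Such sets favour peaks of larger signal and are parts of the conservative list, so they are no independent test of these calls. The stronger 50% of the list ended those of GATA (2.34 points) and Exd/Hox (-0.816 points, adjusted exact p = 0.0707 for both). The GATA difference turned to -1.82 percentage points against windows 500 bp to either side of the same summits (past the threshold in the opposite direction, adjusted exact p = 0.00746) and to -0.616 without replicate 2, and it was 0.934 without replicate 1 and 0 without replicate 3.

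Short sequences were also compared without a prior motif. Of 2080 distinct 6-mers, 66 were more frequent and 95 less frequent at peaks both on 2L, 3L and X and on the held-out arms 2R, 3R and 4. AGAGAG was in 7.56% of peaks and 3.62% of matched weak peaks on the first set of arms (adjusted exact p = 2.08e-09). On the held-out arms it was in 8.81% and 4.06% (adjusted exact p = 7.74e-09). GAGCGA was in 8.37% and 4.11%, and in 8.73% and 4.49% on the held-out arms. Among the rarer ones, CCAGGA was in 1.58% of peaks and 4.87% of weak peaks, and in 1.54% and 5.51% on the held-out arms. Weak peaks lay in coding exons more often than conservative peaks, and leaving summits in coding exons out of both sets, a choice made after that was seen, gave 54 more frequent and 54 less frequent 6-mers. The smaller sets without replicates 1, 2 and 3 gave 8, 4 and 5 6-mers in place of 161.

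Hox, segmentation and signalling genes were bound more often than other protein-coding genes. Of 34 Hox and segmentation genes, 15 were bound (44.1%, against 13.6% of other genes, odds ratio 5.02, adjusted exact p = 0.000101), and the share was 26.5% ± 2.94 (SD, n = 3) in the replicates. The strongest were bcd, which encodes the anterior determinant Bicoid (signal 373), nkd, an inhibitor of Wnt signalling (263), the Hox gene Antp (183) and wg, a Wnt ligand (181). Of 48 developmental signalling genes, 19 were bound (39.6% against 13.6%, odds ratio 4.18, adjusted exact p = 7.84e-05), and 28.5% ± 1.20 (SD, n = 3) in the replicates. The strongest were ci, the transcription factor of Hedgehog signalling (382), sd, the DNA-binding partner of Yorkie (254), pan, the TCF factor of Wnt signalling (240), and bnl, an FGF ligand (213). The genes wg, hh and ptc are on both lists. The genes ci and pan lie on chromosome 4, where the share of bound genes was higher. Genes of cytoplasmic ribosomal proteins were bound in 28 of 91 cases (30.8% against 13.5%, odds ratio 2.84, adjusted exact p = 0.000105) and in 21.6% ± 3.53 (SD, n = 3) in the replicates. RpL7 (264), RpS27 (249), RpL14 (239) and RpL34b (221) had the largest signals. Of 34 genes of chromatin architecture and core promoter factors, 11 were bound (32.4% against 13.6%, odds ratio 3.04, adjusted exact p = 0.0146), and 20.6% ± 7.78 (SD, n = 3) in the replicates. They included Chro (690), lola (223), Taf1 (187) and Cp190 (185), an insulator cofactor.

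Genes of cuticle proteins and sensory receptors were bound less often than other genes. Of 95 cuticle protein genes only Cpr73D (207) was bound (1.05% against 13.7%, odds ratio 0.0668, adjusted exact p = 0.000122). Of 179 sensory receptor genes 2 were bound (1.12% against 13.8%, odds ratio 0.0705, adjusted exact p = 4.61e-08), namely Gr63a (332), a subunit of the carbon dioxide receptor, and Ir21a (85.2). In the replicates the shares were 1.05% in each for cuticle genes and 0.931% ± 0.645 (SD, n = 3) for receptor genes. The other 15 of the 21 lists did not pass the threshold. Of 73 mitochondrial ribosomal protein genes 12 were bound (16.4%, adjusted exact p = 0.609), with mRpS23 (806), mRpS10 (746), mRpL41 (674) and mRpL23 (503) carrying larger signals than the cytoplasmic ones named above. That difference of 2.80 points became 6.13, 6.19 and 6.53 without replicates 1, 2 and 3 (adjusted exact p = 0.0872, 0.0813 and 0.0666). The peaks of mRpS23 and mRpS10 are those named above as nearest to CenG1A and Art3. Of 13 glial genes 5 were bound (38.5%, adjusted exact p = 0.0705), among them moody (294), pnt (154), mdy (117) and repo (109). The glial share was 17.9% ± 4.44 (SD, n = 3) in the replicates, and the difference of 24.8 points fell to 2.83, 2.90 and 3.23 without replicates 1, 2 and 3. The peaks of mdy, repo and the receptor gene Ir21a were in no replicate's thresholded list. The lists of neuronal genes (7 of 37), muscle genes (6 of 33), heat shock proteins (4 of 17), translation factors (9 of 51), aminoacyl-tRNA synthetases (6 of 33) and mitosis genes (6 of 40) also missed it. So did those of proteasome subunits (3 of 48), oxidative phosphorylation subunits (8 of 86), DNA replication (2 of 31), ZAD zinc-finger genes (1 of 16), ecdysone biosynthesis (1 of 15), germline genes (2 of 23) and hemocyte genes (0 of 15, which allows a share of up to 20%). The strongest bound members of these were Csp (506), elav (209), bt (212), Msp300 (202), Hsp27 (411), eIF6 (471), GluProRS (205), dap (189), stg (174), Rpn3 (157), ND-ASHI (193), RnrS (109), Phs (130), shd (161) and bgcn (203).

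All list tests were two-sided Fisher's exact tests adjusted over the 21 lists. In simulated data with nothing planted, at least 1 list was called in 9% of simulations when neighbouring genes shared summits, above the nominal 5%. The simulation left out the effect of TSS number and clusters of bound genes, so the rate for the measured lists is unknown. The chromatin factor call was lost in the stronger 50% of the list (12.2 percentage points, adjusted exact p = 0.0758), among genes with any ranked summit (17.0 points, p = 0.116), without replicate 2 (6.99 points, p = 0.205) and without replicate 3 (1.42 points, p = 0.951). The Hox and segmentation difference was 30.5 points and became 9.87 without replicate 1 (adjusted exact p = 0.0872). The cuticle difference of -12.7 points became -3.83, -4.83 and -4.50 without replicates 1, 2 and 3 (adjusted exact p = 0.276, 0.0627 and 0.0792). For the lists of signalling genes, ribosomal proteins and sensory receptors, the sets without a replicate kept the call, with differences of 9.82 to 14.3, 10.6 to 11.0 and -4.36 to -3.96 points. Fewer genes were bound in these sets. The hemocyte list, with 0 genes bound, stood at -13.7 points in the full list and at -4.87 to -4.47 in them. Points in these sets therefore do not compare with points in the full list. The cuticle values without replicates 2 and 3 are about as low as a list with no bound gene can stand.

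**Figure D4:**
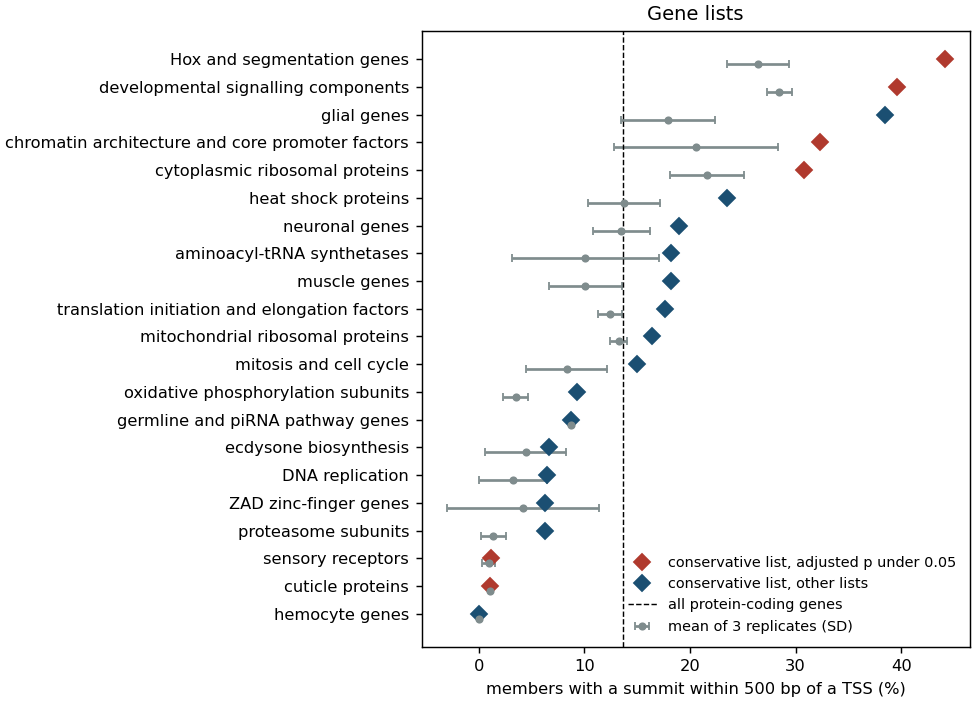
Share of members in percent (x axis) with a summit within 500 bp of a TSS, for each of 21 gene lists (y axis). Diamonds are the conservative list, red where the adjusted p is under 0.05, grey points are the mean and SD of 3 replicates, and the dashed line is the share of all protein-coding genes (13.7%). Hox and segmentation genes stand highest at 44.1%, and cuticle genes (1.05%) and sensory receptors (1.12%) are the lists below the line marked red.

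The annotated locus of CG2199 was examined on 3L from 1339460 to 1342403. No peak lay in the gene body of indra (FBgn0035213) or within 500 bp of its TSSs in the conservative list, in any replicate's list or in the ranked lists, which hold weak peaks too. The nearest conservative summit was 16213 bp away.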

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

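The tests of the ribosomal DNA peaks, of ranked-peak density and ranked-peak signal on chromosome 4 and X were chosen only after these results were seen, and the other tests of this part before. The design has 1 group, so no biological explanation was tested for any pattern.

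A signal appeared in peaks that no comparison used, on the scaffold of ribosomal DNA, whose repeats encode ribosomal RNA. The pooled ranked list held 4 peaks there at or above the score threshold. Replicate 2 held 4 and replicate 3 held 4, while replicate 1 held 1. The thresholded lists leave these peaks out, so their count of 0 there says nothing about signal. There were no control samples to set a background. The strongest scaffold summit of replicates 2 and 3 lay at 73619 in the 28S gene of pre-rRNA:CR45847. It ranked 5 in replicate 2 (signal 351) and 2 in replicate 3 (signal 472) and was in neither the ranked list of replicate 1 nor the pooled one. Spacer summits of the pooled list lay at 64421 (signal 655) and at 66754 (signal 355), the latter 53 bp upstream of the same unit.

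Peaks that reach the score threshold were left out of the thresholded lists, so they were in none of the bound peaks compared. Those on chromosome arms stayed in the ranked lists, which served as backgrounds and for the peak densities and signals of chromosome 4 and X. They numbered 234 for the pooled ranked list and 126, 116 and 130 for replicates 1, 2 and 3. Of the 234, 129 lay on 3R, 61 on 2L, 18 on 3L, 10 on 2R, 1 on X, 4 on the ribosomal DNA scaffold and 11 on other scaffolds.

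The first pattern weighed is the ribosomal DNA signal. Replicate 1 being weaker at all its peaks stays open: it had 1.08 times as many thresholded peaks as replicate 2 but fewer than replicate 3, and signals of different lists have no stated common scale. Replicate 1 missing strong peaks throughout also stays open, since its ranked list held 100% of the peaks on chromosome arms that ranked 1 to 25 in both other replicates, but these were only 17 (lower 95% limit 80.5%). Reads of many ribosomal DNA copies piled on one scaffold stay a candidate explanation. The test of it, whether summits fall in transcribed units by their length (24.9% of the scaffold), had 5 summits with 1 in a unit, too few to decide (exact binomial p = 1). Without control libraries, copy number and binding cannot be told apart here.

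The second pattern is the gene lists bound more or less often than other genes, where the share of bound genes rose from 9.04% with 1 TSS to 71.4% with 9 to 16 TSSs, so TSS number could raise or lower a list. Against genes matched on TSS number the permutation p was 0.001 for ribosomal proteins, 0.0002 for Hox and segmentation genes, 0.0014 for signalling genes, 0.0008 for cuticle genes and 0.0002 for sensory receptors, where 0.0002 is the smallest possible. Among genes whose promoter gave a ranked peak of any strength, adjusted exact p was 0.00226 for each of the first 3 of these lists, 0.00314 for cuticle genes and 0.00203 for receptors. The tables thus argue against TSS number, or merely having a ranked peak, as the whole cause for these 5 lists. They do not decide on promoter openness. Weak peaks, a part of the ranked peaks, lay at promoters in 15.1% of cases and random positions in 13.5%, so a weak peak says little about openness. The promoter share of all ranked peaks was not measured, so how well a ranked peak marks openness is unknown. For chromatin factors TSS number is argued against by a matched p of 0.0406 (32.4% bound against 17.7% ± 6.20 in matched sets), a narrow margin that adjustment over lists would not keep (0.142). Openness cannot be told apart from a preference of the protein for that list: among genes with a ranked peak the odds ratio went only from 3.04 (95% interval 1.33 to 6.5) to 2.42 (1.05 to 5.31) while the adjusted p rose to 0.116 over fewer genes, and a call lost with so similar an odds ratio decides nothing, although the bound set beforehand would count it for openness.

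The third pattern is the arms, with chromosome 4 high and X low. For chromosome 4, higher signal at all ranked peaks (median 1.35 times that on 2L, 2R, 3L and 3R, and 1.24 times over 1 kb from conservative peaks) cannot be told apart from added strong peaks, as peaks of above-median signal were 1.84 times and those of below-median signal 1.02 times as dense. More peaks of any strength there is argued against as the whole cause of the density of conservative peaks. All ranked peaks were 1.44 times as dense as on these 4 arms (95% counting interval 1.37 to 1.51), but conservative peaks numbered 162 per Mb against 39.2 to 48.5. For the share of bound genes it stays open. Among genes with a ranked summit that share was 3.06 times as high (59.2% against 19.4%, 95% interval 2.51 to 3.73). A share of genes is not a density, however, and genes were not matched on TSS number. This test of shares also replaced earlier tests after their values were seen. For X, lower signal at all ranked peaks (median ratio 0.827) cannot be told apart from extra weak peaks that lower the median, as peaks of above-median signal were 0.914 times and those of below-median signal 1.38 times as dense as on these 4 arms. The tests on weak peaks decide nothing, since leaving out sequence near conservative peaks or signals above the median fixes the ratios of genes with a weak peak on 4 (0.521) and of weak-peak signal on X (0.973), and the single X of male embryos stays open, as the sex of the embryos was not recorded.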

How the results depend on the processing

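Differences here are in percentage points unless stated, and for every change the cause was not tested, except that sets without a replicate hold fewer peaks (1327 to 1460) by construction. Those sets favour peaks of larger signal and do not remove the replicate from the making of the conservative list. Fewer genes are bound in them, so their points for arms and gene lists do not compare with those of the full list. Alternatives that leave out coding exons, give the signal agreement of single pairs, search the CG2199 locus in other lists, count each summit for its nearest TSS only or take weak peaks over 100 bp from conservative peaks were chosen after seeing the data. Sharing between replicates, the promoter share, the upstream position and the chromosome 4 share kept their direction and their side of the threshold under every alternative run. The share of divergent promoters did so except with each summit counted for its nearest TSS only, which lowers it by construction and reversed it to -1.61. Among values of results that answer a comparison, 250 did so or, with no test, stayed within 1 SD of the replicates (counts within 1.5 times), 26 moved further, 13 reversed, 7 newly passed and 15 no longer passed. For single motifs 121 did so, 25 reversed, 14 newly passed and 11 no longer passed in the same direction. The unknown read depth limits all statements on weak or missing peaks. No paired analysis was possible because there is only 1 group.

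In the 50% of the list with the larger signal, 5 arms passed in place of 3, with 2L at 1.63 and 2R at -1.56. The 6-mers fell to 67, with 29 higher and 38 lower. The mitosis list reversed to -0.965 and the germline list to 0.234, and the chromatin factors no longer passed at 12.2. The motif differences reversed for Pho (0.142), AP-1 (-0.0355) and Mef2 (-0.142), and GATA (2.34) and Exd/Hox (-0.816) no longer passed.

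In the largest list, Y passed at -18.6, and 269 6-mers passed, 113 higher and 156 lower. The ZAD list reversed to 0.186, as did the motif differences of the E-box (0.0985), AP-1 (-0.0369) and ETS (-0.111), and DRE (0.554), M1BP motif 1 (0.468) and Ohler motif 7 (1.33) newly passed.

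With a promoter window of 250 bp, 2L passed at 1.65 and 3L no longer did at 1.37. At 1000 bp 5 arms passed, among them 3R at -1.59 and Y at -16.7, and 2R reversed to 0.0294. The glial list passed at 29.5, the mitosis list reversed to -1.67 and the germline list to 0.726. Among genes with a ranked summit, the mitosis list reversed to -0.921 and the chromatin factors no longer passed at 17.0.

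A motif window of 100 bp either side of the summit gave 10 motifs past the threshold in place of 6. In it TATA (-0.160) and Zelda (-0.0177) reversed. At 25 bp either side, Ohler motif 6 (-0.0355), TATA (-0.0532), ETS (-0.0887) and E2F (-0.213) reversed. Ohler motif 7 and Inr newly passed in both windows and with flanking windows, Ohler motif 6 and Pho at 100 bp, M1BP motif 1 and E2F with flanking windows, and Ohler motif 7 also without coding exons. Flanking windows gave 11 motifs and 373 6-mers, 212 higher and 161 lower, and reversed the E-box (0.630), TATA (-0.390), AP-1 (-0.0798), Mef2 (-1.75) and GATA (-1.82), the last 2 past the threshold in the opposite direction. Without coding exons 54 6-mers were lower in place of 95, and Ohler motif 6 (-0.0183) and AP-1 (-0.0366) reversed.

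With each replicate left out in turn, the ranges were 1 to 2 arms past the threshold, 0.483 to 0.936 for 3L and -1.28 to -1.09 for X. The signal difference ranged from -0.363 to 4.24 signal units and the signal agreement from 0.60 to 0.671. Between 3 and 5 motifs and 4 to 8 6-mers passed, 0 to 5 higher and 0 to 4 lower. List differences ranged from 9.87 to 13.2 for Hox and segmentation genes, 1.42 to 12.8 for chromatin factors, -4.83 to -3.83 for cuticle genes, 2.83 to 3.23 for glial genes, 6.13 to 6.53 for mitochondrial ribosomal proteins, -1.84 to 1.27 for aminoacyl-tRNA synthetases, -2.37 to 0.534 for mitosis genes and -4.80 to 1.81 for ecdysone biosynthesis. Motif differences ranged from 5.48 to 6.11 for CTCF, 3.84 to 4.45 for BEAF-32, 1.58 to 2.30 for GAGA, -0.431 to 1.03 for Zelda, -0.616 to 0.934 for GATA, -0.216 to 0.301 for Pho, -0.603 to 0.205 for AP-1 and -0.377 to 1.15 for Mef2.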

Other observations

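Genes of small RNAs were compared with protein-coding genes after the data were examined. Of 32 small nuclear RNA (snRNA) genes, whose products take part in splicing, 13 had a conservative summit within 500 bp of a TSS (40.6%, against 13.7% of protein-coding genes, odds ratio 4.33, adjusted exact p = 0.000264). Of 290 tRNA genes, 52 had one (17.9%, odds ratio 1.38, adjusted exact p = 0.0388). The shares were lower for snoRNA genes (7.06% of 269, adjusted exact p = 0.00139), for other noncoding RNA genes (8.48% of 3289, adjusted exact p = 3.94e-16) and for pseudogenes (3.33% of 330, adjusted exact p = 1.13e-09). These are two-sided Fisher's exact tests adjusted over 5 kinds of gene, and neighbouring copies can share a summit. Most of these genes have few TSSs, so they were also set against protein-coding genes matched on TSS number (mean ± SD of 10000 sets). The matched share was 9.12% ± 5.05 for snRNA genes and 9.03% ± 1.66 for tRNA genes (adjusted permutation p = 0.000333 for each, from the smallest p these sets can give). It was 9.10% ± 1.75 for snoRNA genes (adjusted permutation p = 0.281), 9.61% ± 0.427 for other noncoding RNA genes (p = 0.0090) and 9.33% ± 1.58 for pseudogenes (p = 0.000333). The lower share of snoRNA genes was therefore not kept, and that of other noncoding RNA genes was small.

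Transposable elements held few CG2199 summits. Of the 5638 conservative summits, 66 (1.17%) lay in an annotated element, against 6.53% ± 0.320 (SD over 200 random sets) of random positions and 1.56% of weak peaks (odds ratio against weak peaks 0.745, two-sided Fisher's exact p = 0.0222). This comparison was also chosen after the data were seen. How many reads map in repeats is unknown, so the difference from random positions includes what could not be mapped.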
